A study of Mus musculus with 12 samples.

How the data were processed

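Gene expression was measured on 12 Affymetrix mouse arrays, 1 per RNA sample. The samples were 5 primary keratinocyte cultures from newborn mice, 5 skin samples from mice aged 30 days and 2 skin samples from newborn mice. Per the labels, each culture held pooled cells of 5 mice, was kept in medium with little calcium for at most 3 days and was not passaged. The labels give a mixed background of C57, DBA and FVB for 2 cultures and for all 5 samples of 30-day skin, and FVB for 3 cultures and both samples of newborn skin. Strain and age therefore coincide within skin. The labels do not say that the skin samples came from separate animals, so p-values measure the spread between these samples, which may be technical. Groups were assigned from the sample titles.

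The deposited values are on a log2 scale and, per the submitters' processing notes, were made by RMA, a method that corrects background, normalises arrays by quantiles and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The values ran from 2.89 to 13.59, the array medians lay between 5.86 and 6.01, and the sorted values of each array stayed within 0.19 of their mean over arrays. RMA values carry no count or detection call, so the number of arrays limits the precision. Normalising by quantiles assumes similar distributions of RNA in all samples, and differences in cell makeup between skin and culture go against that assumption.

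Of 22690 probe sets, 64 controls were left out of the tests. The platform annotation gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. Of the first, 20351 were matched by gene identifier to the RefSeq gene table and 0 symbols were updated. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 12393 genes, 4956 of them with more than 1 probe set. Genes of families with near-identical copies, such as keratin-associated proteins and late cornified envelope proteins, can share signal between members, and single members are uncertain for that reason.

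Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the Benjamini-Hochberg adjustment over all 12393 genes and a threshold of 0.05 on the adjusted p. All 12 arrays entered 1 fit with a mean per group. The comparison of culture with skin set the cultures against the equally weighted mean of the 2 skin groups, so that age stayed out of the residual spread. Further comparisons set culture against each skin group, and 30-day against newborn skin. A fit with separate means for mixed-strain and FVB cultures measured strain within culture. Errors of log2 differences are standard errors, and errors of group means are SDs.

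Before the data were examined, 36 gene lists were written for skin structures, cell types and processes. Of their symbols, 867 were measured and 156 were not. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move, on balance, one way. The rule for named genes, also set beforehand, took the 10 largest called changes in each direction whose arrays did not overlap, up to 4 called members with the largest change per list and 1 that missed the threshold, and 11 fixed genes of which H19 was not measured. For strain it took the 5 largest changes in each direction. The text names part of the genes so chosen.

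Alternatives covered normalisation, centring of arrays on their median or on the genes of the epithelial junction list, a filter on the dimmest 40% of genes, the probe set rule, thresholds, the variance model, array weights, strain as a covariate, the replicate number as a block, other choices of samples, and leaving out each array in turn. Averaging the arrays that resembled each other most, and the strain covariate without replicate 1 of 30-day skin, were added after seeing the data, as were counts of list members under 4 of these settings. Because strain and age coincide within skin, the strain covariate takes its strain difference from the cultures alone and applies it to skin. Principal components were computed on the centred gene values. Drawings and bookkeeping used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

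The fits were tested on simulated arrays of 12393 genes with the real means and residual SDs, of which 66 or 67 were changed at each of 3 sizes. For culture against skin, 62.7% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 100% of those changed by 2 were recovered. For 30-day against newborn skin these shares were 28.4%, 85.1% and 98.5%. For mixed-strain against FVB cultures they were 14.9%, 79.1% and 98.5%. The SDs came from the fit with 1 mean for all cultures, so they include the difference between strains in culture. Simulated arrays varied independently and few genes were changed, unlike the real data, so the shares are only a guide.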

Results

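The series set skin tissue against keratinocytes grown from skin, and newborn against older animals. Keratinocytes are the epithelial cells of the epidermis, and medium with little calcium keeps them in a basal, proliferating state. Expression of 12393 genes was compared over 5 cultures from newborn mice, 5 samples of 30-day skin and 2 samples of newborn skin. The 1st principal component held 75% of the variance and separated cultures from skin. The 2nd held 11.4% and separated newborn from 30-day skin, and the 3rd, with 4.6%, separated the 2 mixed-strain cultures from the 3 FVB cultures. Replicate 1 of 30-day skin stood apart in its controls. Its 3' actin probe set lay 1.74 above the 5' one on the log2 scale, against 0.67 to 0.82 in the other 4 arrays of its group, and its 18S rRNA signal was 8.40 against 5.2 to 5.9. The actin gap was 0.99 and 1.14 in newborn skin, 0.56 to 0.74 in FVB cultures, and 0.21 and 0.35 in mixed-strain cultures.

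**Figure D1:**
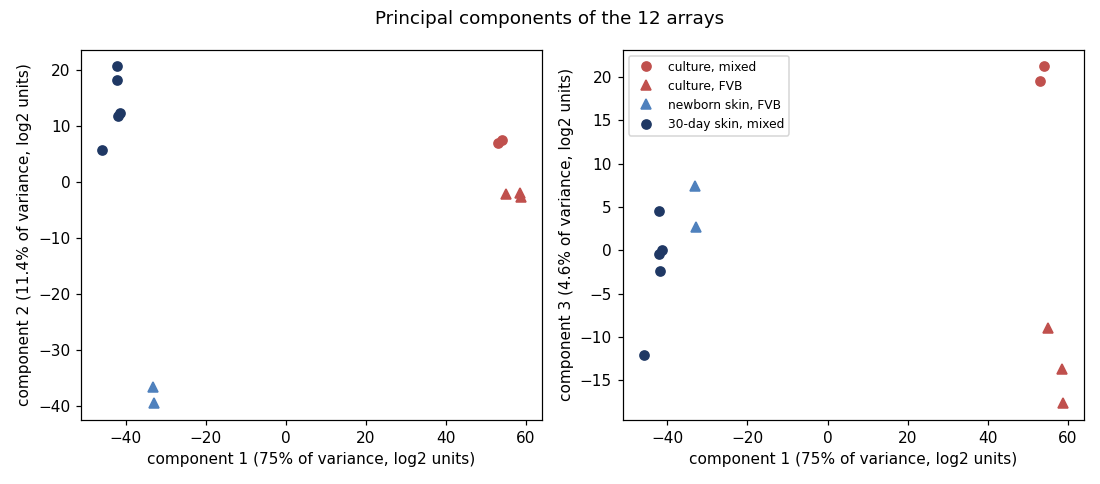
Scores of the 12 arrays on principal components 1, 2 and 3 in log2 units; each point is an array, colours are the 3 groups and shapes the strains. Cultures lie between 53.1 and 58.7 on component 1 and skin between -45.9 and -32.8.

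The 1st comparison asked what distinguishes cultured keratinocytes from skin. Cultures lacked most of the signal of hair, dermis, fat and muscle. Krt25, a keratin of the hair root sheath, averaged 4.39 ± 0.22 (SD, n = 5) in culture, 11.78 ± 0.05 (SD, n = 2) in newborn skin and 12.50 ± 0.13 (SD, n = 5) in 30-day skin, and differed by -7.75 ± 0.10 (SE, adjusted p = 1.23e-15, limma). Of the 42 measured hair keratin and keratin-associated protein genes, 41 were lower in culture and 0 higher, with a median log2 difference of -4.88. Krtap8-1 differed by -7.31 and Krt33a, a hair shaft keratin, by -7.17. Hair follicle regulators were lower for 30 of 45 genes and higher for 4. They included Cd34, a marker of follicle stem cells (-4.06), and Lhx2, a transcription factor of the follicle (-3.40), whereas Fst, an inhibitor of activin, was higher by 3.35.

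Of 37 fibroblast and collagen genes 36 were lower in culture, with a median of -3.34. Col3a1 and Col1a1, which encode fibrillar collagens, differed by -7.13 ± 0.20 and -5.84 ± 0.16 (SE), and the proteoglycan genes Dcn and Lum by -6.01 and -5.80. Adipocyte genes were lower for 18 of 22 and higher for 1. Car3, an abundant enzyme of fat and muscle, differed by -7.87 ± 0.17 (SE), Fabp4 by -7.22 and the adipokine gene Adipoq by -6.58. Car3 read 3.97 to 4.23 in the cultures, below every array median, and signal over background was not measured, so the size and rank of this and other differences from such low values are uncertain. Skeletal muscle genes were lower for 28 of 29 and higher for 1, among them the sarcomere genes Tnnc2 (-6.99), Myl1 (-6.83), Myh1 (-5.93) and Acta1 (-5.79). With an estimated correlation the muscle list had an adjusted p = 0.053.

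Markers of blood vessels, macrophages and mast cells were lower as well. The counts were 21 of 24 endothelial genes, 14 of 17 smooth muscle and pericyte genes, 29 of 33 macrophage genes and 9 of 14 mast cell genes, each with 0 higher. The water channel gene Aqp1 differed by -3.70, desmin (Des) by -2.81, the mannose receptor gene Mrc1 by -3.55, the complement gene C1qa by -3.39 and the mast cell protease gene Cpa3 by -2.93. Among Langerhans cell and MHC class II genes 9 of 20 were lower and 1 higher (adjusted p = 0.18 with an estimated correlation). Sebaceous gland genes were lower for 14 of 18 and higher for 3, with Elovl3, a fatty acid elongase, at -3.12. Melanocyte genes were lower for 10 of 16 and higher for 1 (adjusted p = 0.45 with an estimated correlation), including Trpm1 (-1.98) and Tyr, which encodes tyrosinase (-1.81). This depended on the strain of the cultures and the age of the skin. The list mean was 7.36 and 7.37 in mixed-strain and 6.45 to 6.53 in FVB cultures, against 7.09 in newborn and 7.58 to 7.96 in 30-day skin. Against newborn skin alone 3 genes were higher and 6 lower (camera adjusted p = 0.27).

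Within the epidermal programme, cornified envelope genes were lower in culture for 24 of 29 and higher for 2, with loricrin (Lor) at -3.85 ± 0.11 and hornerin (Hrnr) at -4.07 ± 0.19 (SE). Spinous differentiation genes were lower for 12 of 19 and higher for 1 (adjusted p = 0.28 with an estimated correlation). The suprabasal keratin genes Krt10, Krt77 and Krt1 differed by -4.16, -4.60 and -2.86. Barrier lipid synthesis genes were lower for 13 of 21 and higher for 4, with the fatty acid hydroxylase gene Fa2h at -2.74. Basal keratinocyte and hemidesmosome genes were higher for 13 of 20 and lower for 2 (adjusted p = 0.16 with an estimated correlation), or 10 and 6 under epithelial centring, which centres arrays on the epithelial junction genes. The laminin-332 genes Lama3 and Lamb3 rose by 3.11 and 2.54 and Col17a1 by 2.13, while the basal keratins Krt5 and Krt14 rose by 1.09 ± 0.09 and 1.15 ± 0.09 (SE). Krt15, a keratin of quiescent basal and bulge cells, went the other way by -4.79.

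Genes of activated keratinocytes, known from wound repair, were higher in culture for 23 of 33 and lower for 4 (adjusted p = 0.10 with an estimated correlation), or 19 and 9 under epithelial centring. Krt16 rose by 4.31, the plasminogen activator inhibitor gene Serpinb2 by 3.89, S100a9 by 3.52 and Il1a by 2.99. Matrix remodelling and migration genes were higher for 18 of 30 and lower for 4, a balance that ended at 12 and 12 under epithelial centring, with thrombospondin 1 (Thbs1) at 3.80, Adam8 at 3.69 and Itgb6 at 2.78. Of 22 p53 and senescence genes 15 were higher and 1 lower, or 12 and 6 under epithelial centring. Pmaip1, a pro-apoptotic p53 target, went from 4.86 ± 0.02 (n = 2) and 4.78 ± 0.18 (n = 5) in the skin groups to 9.95 ± 0.10 (SD, n = 5) in culture. Mdm2 and Zmat3 rose by 2.20 and 1.88. Bcl2l15, a relative of Bcl2, rose by 5.50 ± 0.16 (SE), and Ptgs2, the inducible cyclooxygenase gene, rose by 4.06. Cholesterol synthesis genes were higher for 13 of 19 and lower for 0, or 9 and 5 under epithelial centring, with Sc5d at 1.71 and Fdps at 1.10. Epithelial junction genes were higher for 12 of 22 and lower for 4 (adjusted p = 0.34 with an estimated correlation), or 10 and 0 with close arrays averaged, including Cldn4 (2.22) and Cdh1, which encodes E-cadherin (1.11). Interferon response genes were higher for 12 of 24 and lower for 4 (adjusted p = 0.45 with an estimated correlation), a direction that turned to 6 higher and 12 lower under epithelial centring, and with close arrays averaged 7 were higher and 2 lower.

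The cell cycle lists gave no camera call against the mean of both ages of skin, which differed from each other. Of 32 DNA replication genes 7 were higher and 3 lower (camera adjusted p = 0.26), and of 34 mitosis genes 10 were higher and 6 lower (camera adjusted p = 0.52). Both balances turned under epithelial centring, to 3 higher and 20 lower and to 1 higher and 18 lower. Rrm2, a subunit of ribonucleotide reductase, rose by 1.03, and Mki67, the gene of the proliferation marker Ki-67, fell 2.82-fold, to 7.67 ± 0.53 (SD, n = 5). In all, 5829 genes or 47% passed the threshold, 3054 higher and 2775 lower in culture, and 513 and 939 of these differed at least 2-fold. Arrays did not overlap for 1895 of the genes that were higher and 1694 of those that were lower, whereas chance separates 5 from 7 arrays in 0.253% of genes. For the lists described so far the counts adjusted over the list alone were the same except for fibroblast (37 lower), hair regulators (5 higher and 31 lower), macrophage (30 lower), Langerhans cell (2 and 10), sebaceous gland (15 lower), p53 (17 higher), epithelial junction (5 lower) and DNA replication genes (6 higher). Relative to the epithelial junction genes the median gene shifted by -0.481, and the calls became 895 higher and 8736 lower. The junction genes were themselves higher in culture, by a mean of 0.49 (camera adjusted p = 0.024). Centring on them lowers every gene in culture by that much, so the turned balances follow from the reference chosen. Which reference is right was not tested.

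**Figure D2:**
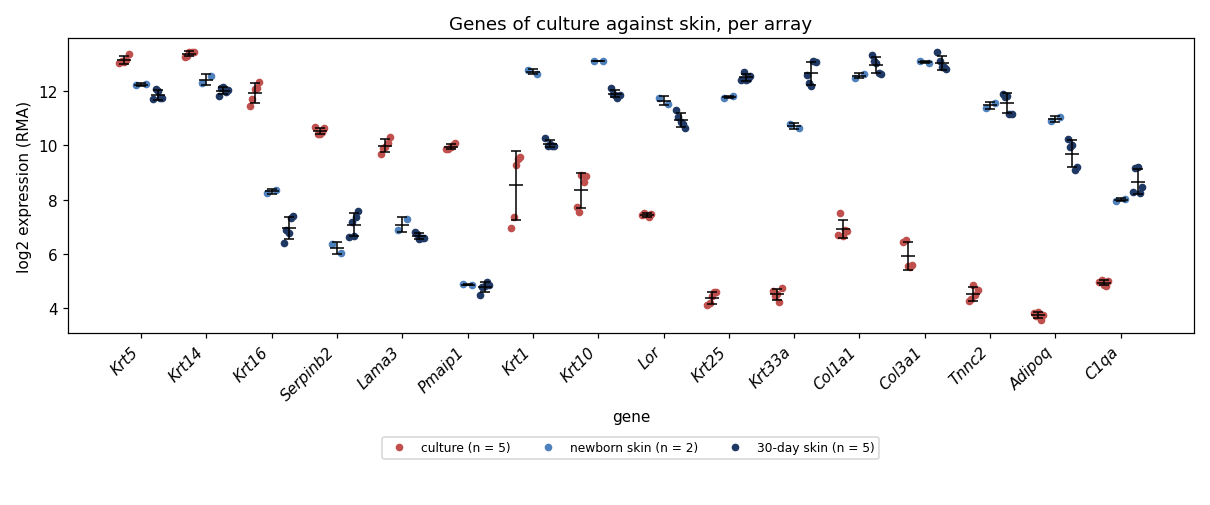
Log2 expression of 16 genes in each array (points) for culture, newborn skin and 30-day skin, with group means (bars) and SDs (whiskers). Krt5 averages 13.14 in culture against 12.24 and 11.86 in newborn and 30-day skin, while Col3a1 averages 5.92 against 13.07 and 13.03.

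Set against each age of skin separately, cultures differed in 4522 genes from newborn skin, 2223 higher and 2299 lower, and in 5989 genes from 30-day skin, 3280 higher and 2709 lower. Under epithelial centring these counts were 406 and 9561 against newborn skin, and 1672 and 5603 against 30-day skin, where the balance turned. With close arrays averaged they were 1252 and 1517 against newborn skin. Without newborn skin replicate 1 the genes higher against newborn skin numbered 1398. The gap between these contrasts for a gene equals the age difference in skin, which is tested next. Igf2, a fetal growth factor gene, was lower than newborn skin by -4.48 but higher than 30-day skin by 0.40 (adjusted p = 4.67e-11 and 0.0169, limma). Igf2bp3, an RNA-binding protein gene of fetal tissue, did not pass the test against newborn skin (0.04, adjusted p = 0.89) and was higher than 30-day skin by 2.77. The wound keratin gene Krt6b was higher than 30-day skin by 4.01, while against newborn skin its cultures lay on both sides, at means of 8.09 in mixed-strain and 9.64 in FVB cultures and 8.91 in newborn skin. Krt77, a keratin of sweat ducts and interfollicular epidermis, was lower by -2.86 and -6.35.

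Some lists also stood differently against the 2 ages of skin. DNA replication genes were 3 higher and 6 lower than in newborn skin (camera adjusted p = 0.13) but 17 higher and 0 lower than in 30-day skin (camera adjusted p = 0.00035, or 0.42 with an estimated correlation). Mitosis genes were 2 higher and 8 lower (camera adjusted p = 0.18), and 18 higher and 4 lower (camera adjusted p = 0.0095, or 0.56 with an estimated correlation). Under epithelial centring the counts of DNA replication genes were 0 and 29 against newborn skin and 9 and 1 against 30-day skin, and those of mitosis genes 0 and 25, and 8 and 6. With strain as a covariate the counts against 30-day skin were 8 and 1 for DNA replication and 10 and 5 for mitosis genes, and those against newborn skin 3 and 3, and 3 and 9. With close arrays averaged the counts against newborn skin were 0 and 2 for DNA replication and 0 and 4 for mitosis genes. Imprinted and fetal growth genes, such as Igf2, were 5 higher and 19 lower than in newborn skin (adjusted p = 0.029 with an estimated correlation) and 9 higher and 11 lower than in 30-day skin (camera adjusted p = 0.45). Interferon response genes were 14 higher and 1 lower than in newborn skin (adjusted p = 0.16 with an estimated correlation; 5 and 10 under epithelial centring, 6 and 0 with close arrays averaged) and 6 higher and 5 lower than in 30-day skin (camera adjusted p = 0.60; 6 and 8 under that centring).

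The comparison of 30-day with newborn skin asked what changes with postnatal age, with strain changing alongside. Imprinted and fetal growth genes fell in 30-day skin. Igf2 averaged 11.91 ± 0.03 (SD, n = 2) in newborn and 7.04 ± 0.30 (SD, n = 5) in 30-day skin, a 29.3-fold difference (-4.87 ± 0.17, SE, adjusted p = 8.25e-11, limma). Dlk1 and Mest, both paternally expressed, fell by 4.55 and 3.89, and Igf2bp3 fell by 2.74. Of 32 measured members of the list 20 were lower and 1 higher, also when adjusted over the list alone, and the camera call held with an estimated correlation (adjusted p = 0.011). Agtr2, an angiotensin receptor gene active in fetal tissue, fell by 3.78.

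Developmental muscle genes fell in 30-day skin and some adult isoform genes rose. The embryonic and perinatal myosin heavy chain genes Myh3 and Myh8 fell by 4.63 ± 0.11 and 6.42 ± 0.11 (SE), and the cardiac actin gene Actc1 fell by 3.17. Of 18 developmental muscle genes 13 were lower and 0 higher, or 14 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.011). Myh4, the fast adult myosin gene, rose from 4.49 ± 0.04 (n = 2) to 10.75 ± 0.33 (SD, n = 5), the calcium buffer gene Pvalb by 5.18 and Myh2 by 3.09. Skeletal muscle genes were higher for 11 of 29 and lower for 1, or 13 and 1 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). Acta1 differed by -0.13 (adjusted p = 0.833).

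Hair keratin and keratin-associated protein genes were higher in 30-day skin for 39 of 42 and lower for 0, or 41 adjusted over the list alone, with a median of 1.96 (adjusted p = 0.083 with an estimated correlation). Krtap14 rose by 3.18 ± 0.34 and Krtap4-2, a gene of the same family outside the list, by 3.12 ± 0.22 (SE). Hair follicle regulators went both ways, 9 higher and 7 lower of 45, or 12 and 11 adjusted over the list alone, with 4 higher and 22 lower under epithelial centring, 8 and 4 with strain as a covariate and 2 and 3 with close arrays averaged. Hoxc13 and Foxn1, transcription factors of hair shaft differentiation, rose by 1.41 and 1.35, and Sox18, a factor of vessels and dermal papilla, fell by 1.66.

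Some immune genes were higher in 30-day skin. H2-Aa, Cd74 and H2-Eb1, of the MHC class II pathway, rose by 3.62, 3.25 and 3.02. Of 20 genes of the Langerhans cell and MHC class II list 6 were higher and 0 lower, or 7 adjusted over the list alone, with a median of 0.09 (adjusted p = 0.091 with an estimated correlation). Macrophage genes were higher for 13 of 33 and lower for 1, or 16 and 1 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation), with Cd163 at 1.28 and Lyz2 at 1.80. With strain as a covariate the macrophage count was 4 higher and 1 lower, and with close arrays averaged it was 3 and 0. The chemokine gene Ccl8 rose by 4.27. Interferon response genes were higher for 9 of 24, or 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.091 with an estimated correlation), including Psmb8 and Gbp2, both at 1.03. With strain as a covariate Lyz2 and Gbp2 did not pass (0.54 and 0.41). Without replicate 1 of 30-day skin, whose mean of this list stood apart, 6 were higher and 1 lower. Mast cell genes fell for 6 of 14, or 7 adjusted over the list alone (adjusted p = 0.083 with an estimated correlation), with the proteases Cma1 at -2.25, Cpa3 at -2.18 and Tpsb2 at -1.89. Under epithelial centring the macrophage count became 7 higher and 7 lower.

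Some fibroblast and endothelial genes were lower in 30-day skin. Of 37 fibroblast and collagen genes 21 were lower and 1 higher, or 23 and 1 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). The elastic fibre genes Eln and Mfap2 fell by 1.97 and 1.78 and the dermal transcription factor gene Twist2 by 2.42, whereas Col1a1 differed by 0.38 (adjusted p = 0.287). Endothelial genes were lower for 11 of 24, or 12 adjusted over the list alone (adjusted p = 0.091 with an estimated correlation), with Cldn5 at -1.17 and Cdh5 at -1.07. Smooth muscle and pericyte genes were lower for 3 of 17 and higher for 1 (camera adjusted p = 0.62), or 4 and 2 adjusted over the list alone.

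In the epidermis, cornified envelope genes were lower for 15 of 29 and higher for 4, or 16 and 4 adjusted over the list alone (adjusted p = 0.083 with an estimated correlation). Hrnr fell by 2.96 and Lce1h by 2.95, and Lor by 0.72. Krt1 and Krt10 fell by 2.65 and 1.21, calls that ended with strain as a covariate (to -0.36 and -0.03). The calls also rest on keeping both newborn arrays, although each of them lay above every 30-day array. Krt1 was 12.78 and 12.64 in newborn skin against 9.97 to 10.27, and Krt10 was 13.11 in both against 11.76 to 12.10. The spread used for these tests includes the cultures, which split by strain. Krt1 was 6.94 and 7.35 in mixed-strain and 9.27 to 9.56 in FVB cultures, and Krt10 was 7.73 and 7.54 against 8.66 to 8.91. Krt77 rose by 3.49 ± 0.11 (SE). Krt6b fell by 3.90 and Stfa3, a stefin gene, by 6.25 ± 0.54 (SE). Krt14 differed by -0.41 (adjusted p = 0.031), which did not pass with strain as a covariate (-0.24), and Krt5 by -0.38 (adjusted p = 0.0601).

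DNA replication genes were lower in 30-day skin for 20 of 32 and mitosis genes for 19 of 34, each with 0 higher, or 25 and 22 adjusted over the list alone (adjusted p = 0.12 and 0.19 with an estimated correlation). The helicase subunit genes Mcm5 and Mcm7 fell by 1.09 and 1.03, Rfc3 by 1.19, Birc5 by 0.90 and Cdk1 by 0.88, whereas Mki67 differed by -0.53 (adjusted p = 0.255). With strain as a covariate the counts were 3 and 2, and none of these 5 called genes passed. Melanocyte genes were higher for 5 of 16 and lower for 0, or 8 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). Gpnmb rose by 2.39, Oca2 by 1.74 and Tyrp1 by 1.99. Tyrp1 turned to -0.30 with strain as a covariate, and the list to 1 higher and 3 lower.

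In all 1952 genes or 15.8% differed between the ages, 732 higher and 1220 lower in 30-day skin, and 204 and 272 of these at least 2-fold. The counts were 256 and 418 without newborn replicate 2, and 305 and 594 without newborn replicate 1; the remaining newborn array was then assumed to vary like the other groups. With strain as a covariate they were 659 and 733, and 870 of the 1952 genes were called in the same direction. Under epithelial centring they were 254 and 6503, and with close arrays averaged 151 and 259. The strain covariate rests on the cultures, where genes of hair, muscle and other parts missing from culture have little signal. Counts of such genes under it therefore cannot test strain in skin. For genes with signal in culture, it carries a difference between keratinocyte cultures over to whole skin. The list counts with strain as a covariate were, higher and lower, 30 and 0 for hair keratin, 1 and 19 for imprinted, 0 and 13 for developmental muscle, 9 and 2 for skeletal muscle, 0 and 25 for fibroblast, 0 and 12 for endothelial, 3 and 11 for cornified envelope, 5 and 1 for Langerhans cell, 6 and 0 for interferon and 0 and 5 for mast cell genes. With the 4 closest pairs of arrays averaged, newborn replicates 1 and 2 among them, the same lists counted 27 and 0, 0 and 17, 0 and 9, 8 and 0, 0 and 7, 0 and 3, 0 and 6, 5 and 0, 3 and 0, and 0 and 4, while DNA replication, mitosis and melanocyte genes counted 0 and 3, 0 and 1, and 2 and 0.

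**Figure D3:**
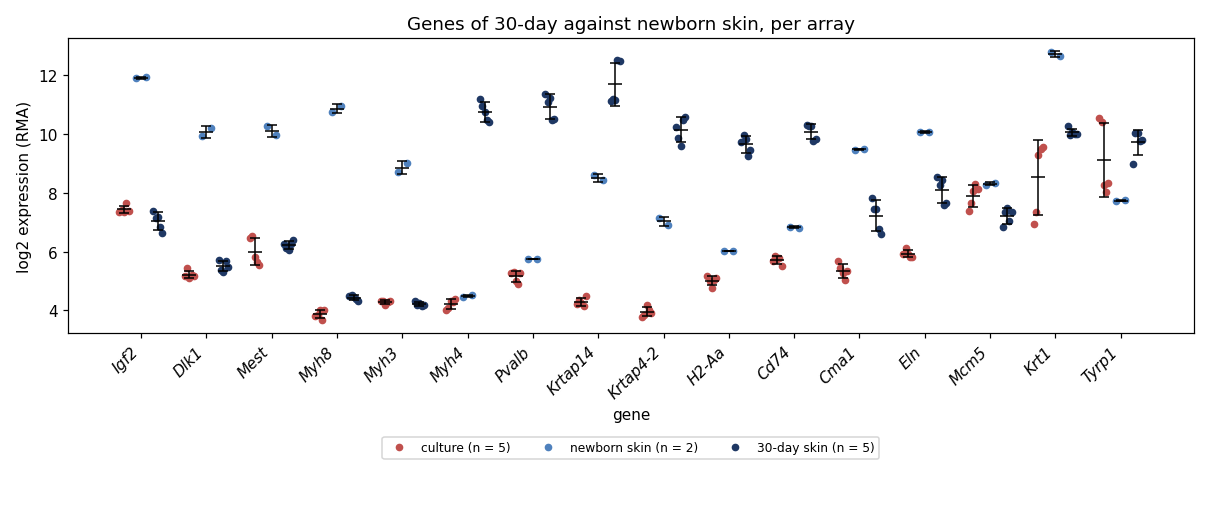
Log2 expression of 16 genes in each array (points) for culture, newborn skin and 30-day skin, with group means (bars) and SDs (whiskers). Myh8 averages 10.86 in newborn and 4.44 in 30-day skin, and Myh4 averages 4.49 and 10.75.

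**Figure D4:**
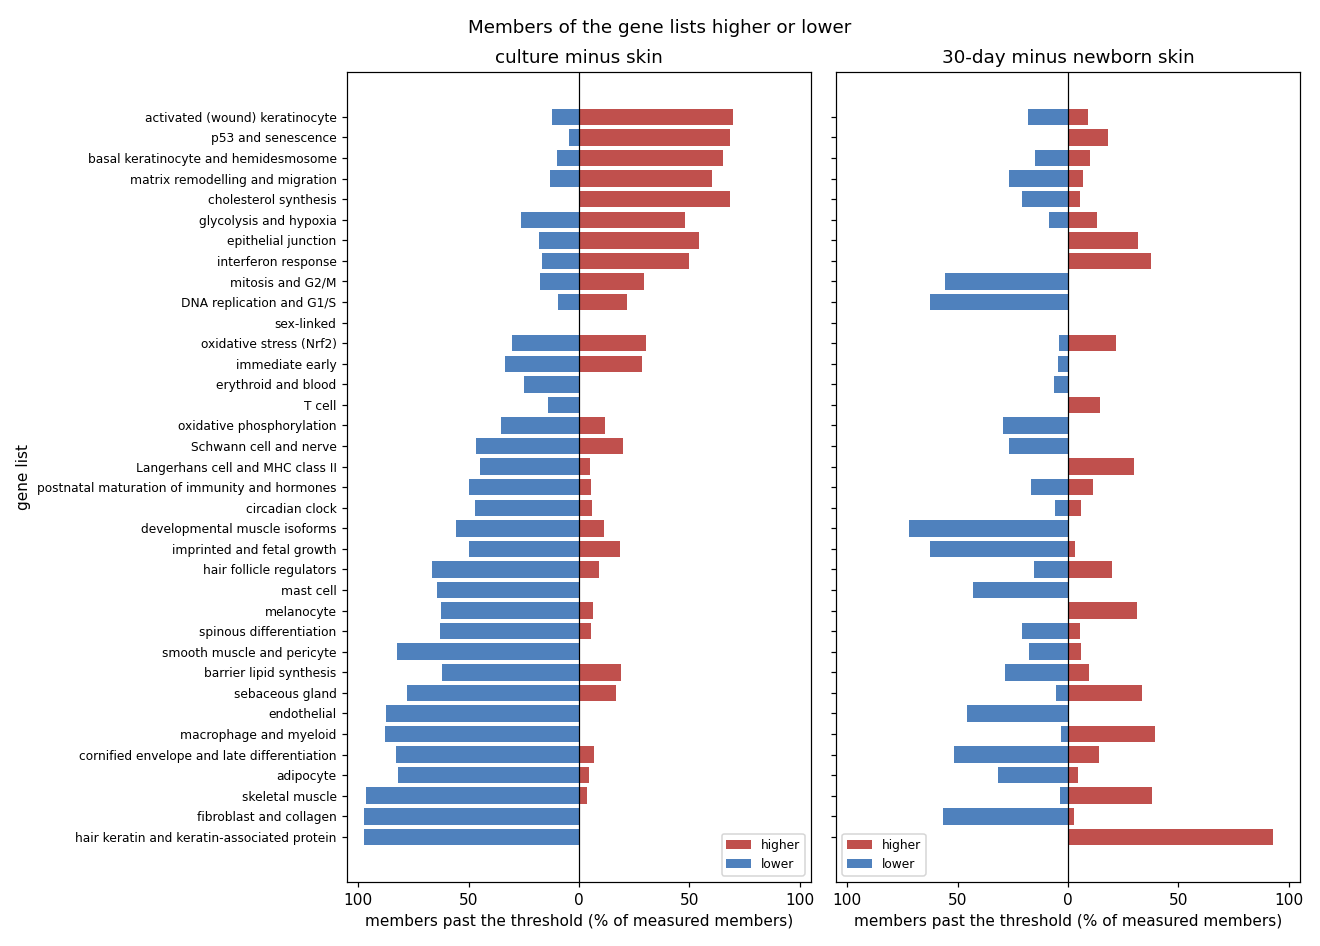
Percent of the measured members of each of the 36 gene lists past the adjusted p threshold, drawn to the right when higher and to the left when lower, for culture minus skin and for 30-day minus newborn skin. Hair keratin genes are lower in culture for 41 of 42 members and higher in 30-day skin for 39.

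Strain was compared where age and material were shared, among the cultures. The 2 mixed-strain cultures had more melanocyte signal than the 3 FVB cultures. FVB is an albino strain, and whether this bears on the difference was not tested. Of 16 melanocyte genes 9 were higher and 0 lower, or 11 and 1 adjusted over the list alone, and the camera call held with an estimated correlation (adjusted p = 0.026). Tyrp1, a pigment enzyme gene, averaged 10.48 in mixed-strain and 8.19 in FVB cultures (2.29 ± 0.23, SE, adjusted p = 2.89e-05, limma). Fibroblast and collagen genes were higher for 12 of 37 and lower for 0, or 14 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). Spinous differentiation genes were lower in the mixed-strain cultures for 9 of 19 and higher for 0, or 12 adjusted over the list alone, and DNA replication genes were lower for 14 of 32 and higher for 0, or 21 adjusted over the list alone. Both calls held with an estimated correlation (adjusted p = 0.026). The 2 mixed-strain cultures were the most alike of all arrays (SD of their differences 0.158 on the log2 scale), and the labels do not say whether they came from separate pools of cells. With them averaged into 1, as were the other close pairs, the counts in the stated directions were 4 melanocyte, 4 fibroblast, 4 spinous and 2 DNA replication genes.

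The cytokine genes Il1a and Il33 were higher in mixed-strain cultures by 2.41 and 2.35, Rpgrip1 by 2.84 and D17H6S56E-5 by 3.69. Krt1 was lower by -2.29, Gdpd3 by -2.52, Chl1 by -2.24, the gap junction gene Gjb2 by -2.23 and Spon2 by -2.19. In all 1219 genes passed, 394 higher and 825 lower, with close arrays averaged 55 and 69, and under epithelial centring, where the balance turned, 263 and 236. Without mixed-strain replicate 1 these counts were 117 and 155, without replicate 2 they were 153 and 255, and without FVB replicate 4 the lower count was 464. Without 30-day replicate 1, which enters the shared spread, the higher count was 648. The 3' to 5' actin gap differed between these cultures too.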

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

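The tests of strain, RNA quality and fibroblasts were chosen after the results they bear on were seen, whereas the counts of other sample splits were planned. An array was listed here when its distance from the rest of its group was large for the range of that group, a criterion that chance meets in about 1 of 20 groups. Of 310 groups tested 21 met it, against 15.5 by chance, and 13 of the 21 concerned replicate 1 of 30-day skin.

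In replicate 1 of 30-day skin the 3' minus 5' gap was 1.74 for actin and 0.71 for Gapdh (others 0.09 to 0.21), and the 18S rRNA control was 8.40. Its mean over the epithelial junction genes was 8.82 (others 9.19 to 9.21), over the interferon genes 6.16 (5.74 to 5.82) and over the sebaceous genes 8.44 (8.09 to 8.19). Among genes it held Krt27 at 11.80, Thbs1 at 5.63, Actc1 at 8.53, Rfc3 at 4.59, Stfa3 at 6.88, Gpnmb at 8.69 and Tyrp1 at 8.99. If the RNA of this array made the age differences, leaving it out should remove most of them. The calls numbered 2231 without it, and 1847 of the 1952 genes were called in the same direction, so most do not rest on this array. The rise itself is no evidence, because the array enters the shared spread. Calls for strain in culture, which it is not part of, rose too, from 394 to 648 higher. RNA quality between the ages stays open, since the actin gap was 0.99 and 1.14 in newborn skin and 0.67 to 0.82 in the other 30-day arrays. What set this array apart stays open, and no biological explanation was tested for it.

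Elsewhere Bcl2l15 was 4.77 in 30-day replicate 4 (others 4.35 to 4.38). Among cultures, Col1a1 was 7.51 in replicate 2, Cd34 was 4.58 and Cdh1 9.90 in replicate 5, Igf2 was 7.64 and Agtr2 4.15 in replicate 4, and Myh3 was 4.17 and Foxn1 5.31 in replicate 3.

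Among probe sets without a single gene name, which entered no gene count, 679 passed the threshold between culture and skin and 213 between the ages.

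Age and strain change together in skin, and the cultures show how far strain, with any culture batch that coincides with it, moves the same genes. For the imprinted and fetal growth genes the comparison covers the 13 of 32 members at or above the median gene level in culture. They differed by a median of 0.14 between mixed-strain and FVB cultures (95% bootstrap interval over genes -0.07 to 0.44), against -2.01 in skin. For these 13 members the values argue against strain, provided that strain acts in skin as it does in cultured keratinocytes. Dlk1 and Mest lay below that level in culture and stay untested. Over 23 of 32 DNA replication genes the median was -0.51 (-0.70 to -0.37) between cultures and -0.65 in skin. Strain may therefore account for much of that decrease. All these intervals resample genes, not arrays, so they leave out the spread between cultures. The mixed-strain cultures may share 1 pool of cells, and with close arrays averaged 2 of the 32 genes were called lower in them. Melanocyte genes were higher in the older skin, and 8 of 16 members were compared. Their median was 0.84 (0.26 to 2.15) between cultures and 0.55 in skin. Strain may account for part or all of that increase, but the interval is too wide to say how much. Whether the cultures differed in their share of melanocytes was not tested. For hair keratin genes strain and age cannot be told apart, because 6 of 42 members reached that level in culture (median 0.29, against 2.45 in skin), and members below it stay untested in every list; age itself remains open as an untested explanation.

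Fibroblast genes were higher in the mixed-strain cultures, and whether fibroblasts carried over from skin account for it stays open. The 10 list members most abundant in newborn skin were higher by a median of 0.65 (0.46 to 1.14), from 1.37 for Vim to 0.22 for Dcn, but they belong to the list that showed the difference, and a strain difference in these genes would give the same values. Other lists of cells outside the epidermis gave fewer calls. Macrophage genes were higher for 5 of 33, smooth muscle and pericyte genes for 3 of 17 and Schwann cell genes for 3 of 15, each with 0 lower. With close arrays averaged these counts were 3, 2 and 1. Camera called these lists higher (adjusted p = 4.9e-05, 0.0041 and 0.008), but no call held with an estimated correlation (adjusted p = 0.098, 0.12 and 0.098). Endothelial genes gave 1 higher and mast cell genes 0 (camera adjusted p = 0.051 and 0.49). A culture batch that coincides with strain cannot be told apart from strain, because the labels allow 0 splits by batch within a strain. A difference of strain itself stays open.

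For culture against skin, 1 of 100 drawn splits of the 12 arrays, the real one, reached its 5829 genes, and the highest other gave 2678. For culture against 30-day skin, again 1 of 100 of the 126 splits, the real one, reached its 5989 genes, and the highest other gave 7. A chance division of the arrays is thus an unlikely source of either count, and 1 of 100 is the lowest share these draws can give. The splits treat arrays as independent, which the close pairs may not be.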

How the results depend on the processing

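The averaging of close arrays, and the strain covariate without 30-day replicate 1, were chosen after seeing the data; the other settings were planned. Pairs of counts are genes higher and lower, and the cause of each change was not tested unless the setting itself gives it. Quantile normalisation, median centring, the filter on dim genes, the mean over probe sets, the trended robust fit, the fits on newborn, tissue or culture and 30-day arrays, the single-strain fits, 2 pooled groups and leaving out 30-day replicates 4 and 5 kept all counts within 1.5 times; called genes were called in the opposite direction under epithelial centring (101 against skin, 127 against newborn skin) and with the mean over probe sets (7 against skin, 4 against newborn skin, 7 against 30-day skin, 1 for strain). Another probe set of the same gene was called the opposite way for 99, 46 and 99 called genes in these 3 comparisons of culture, 4 between ages and 8 for strain. Signal over background was not measured, so limits for dim genes are unknown.

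Centring on the epithelial junction genes shifted the median gene by -0.481 against skin (895 and 8736, 9.3% higher instead of 52.4%), by -0.689 against newborn skin (406 and 9561), by -0.267 against 30-day skin (1672 and 5603) and by -0.431 between ages (254 and 6503); strain gave 263 and 236, or 52.7% higher instead of 32.3%. Those shifts largely follow from the reference. The junction genes themselves differed by means of 0.49 against skin, 0.70 against newborn skin, 0.28 against 30-day skin and 0.42 between ages. Centring on the median shifted culture against 30-day skin by 0.102. Testing every probe set, which adds tests, gave 5491 higher against skin, 3972 against newborn skin, 5689 and 4109 against 30-day skin and 885 for strain. An adjusted p under 0.01 left 368 and 632 between ages and 188 and 318 for strain. Asking for 2-fold left 513 and 939 against skin, 555 and 1017 against newborn skin, 588 and 941 against 30-day skin, 204 and 272 between ages and 75 and 78 for strain. Array weights gave 1278 and 1971 between ages, the strain covariate 733 lower, and 30-day skin against all newborn arrays 1472 and 2004. The culture arrays alone gave 639 higher for strain. Averaging close arrays (culture 1 and 2, 30-day 2 and 3, 30-day 4 and 5, newborn skin 1 and 2), which leaves fewer samples, gave 1252 and 1517 against newborn skin, 151 and 259 between ages and 55 and 69 for strain.

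Leaving out each array in turn gave 2602 to 3127 and 2417 to 2827 against skin, 1398 to 2364 and 1643 to 2416 against newborn skin, 3067 to 3300 and 2505 to 2687 against 30-day skin, 256 to 864 and 418 to 1367 between ages, and 117 to 648 and 155 to 1166 for strain. Highest counts mostly came without 30-day replicate 1, lowest between ages without newborn replicate 2 and for strain without culture replicate 1.

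Same-numbered arrays correlated between -0.28 and 0.23 in their deviations, and differently numbered ones reached -0.23 and 0.22. These values gave no sign that the numbers pair samples, but they cannot exclude it. With the replicate block the counts were 2690 and 2503 against skin, 513 and 852 between ages and 267 and 539 for strain.

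Tyrp1 between ages reversed to -0.30 with the strain covariate and to -0.12 without 30-day replicate 1 as well. Against all newborn arrays, where cultures dominate, these reversed: Actc1 0.11, Sox18 0.35, Cma1 0.69, Cpa3 0.70, Tpsb2 0.02, Eln 0.99, Mfap2 1.24, Krt1 0.34, Krt10 2.20, Lor 2.29, Hrnr 1.0, Cldn5 0.30, Cdh5 0.52, Adipoq 3.87 and Acta1 4.05. With an estimated correlation 57 list calls were lost.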

Other observations

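The list counts under epithelial centring, under the strain covariate and with close arrays averaged, and the comparison of the age and strain contrasts were chosen after results were seen. For 12 further lists no camera call between culture and the mean of both ages of skin held with an estimated correlation. Glycolysis and hypoxia genes were higher in culture for 11 of 23 and lower for 6, with Slc2a1, the gene of a glucose transporter, higher by 2.97. Immediate early genes split 6 higher and 7 lower of 21, with Myc at 1.82 and Fos at -1.55. Oxidative phosphorylation genes were lower for 12 of 34 and higher for 4, circadian clock genes lower for 8 of 17 and higher for 1, Nrf2 targets 7 higher and 7 lower of 23, Schwann cell genes 3 higher and 7 lower of 15, and blood genes 4 lower of 16. None of these 7 lists passed camera. Under epithelial centring the counts higher and lower were 7 and 9 for glycolysis, 4 and 15 for immediate early, 0 and 30 for oxidative phosphorylation, 1 and 15 for circadian, 1 and 15 for Nrf2, 2 and 12 for Schwann cell and 0 and 16 for blood genes. With close arrays averaged they were 11 and 4, 6 and 6, 3 and 3, 1 and 5, 5 and 4, 3 and 4, and 0 and 4. Developmental muscle, imprinted and postnatal maturation genes were lower for 10 of 18, 16 of 32 and 9 of 18 and higher for 2, 6 and 1 (adjusted p = 0.089, 0.08 and 0.053 with an estimated correlation). T cell genes were lower for 3 of 21, or 0 adjusted over the list alone, and of 7 sex-linked genes 0 passed.

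Between the ages, oxidative phosphorylation genes were lower in 30-day skin for 10 of 34 and higher for 0 (adjusted p = 0.12 with an estimated correlation), with Atp5o, a subunit of ATP synthase, at -0.72. Epithelial junction genes were higher for 7 of 22 and lower for 0 (adjusted p = 0.093 with an estimated correlation), or 12 and 0 without replicate 1 of 30-day skin. Sebaceous gland genes were higher for 6 of 18 and lower for 1 (adjusted p = 0.12 with an estimated correlation), or 2 and 5 under epithelial centring. Defb6, a defensin gene of that list, rose by 3.34, and Adipoq fell by 1.29. Adipocyte genes were lower for 7 of 22 and higher for 1 (adjusted p = 0.24 with an estimated correlation), T cell genes higher for 3 of 21 (0.12), Nrf2 targets higher for 5 of 23 and lower for 1 (0.083), p53 genes higher for 4 of 22 (0.083) and Schwann cell genes lower for 4 of 15 (0.24). Under epithelial centring Nrf2 targets gave 2 and 4, p53 genes 1 and 5 and T cell genes 0 and 2. With strain as a covariate the counts higher and lower were 0 and 5 for oxidative phosphorylation, 4 and 0 for epithelial junction, 2 and 0 for sebaceous gland, 2 and 9 for adipocyte, 0 and 0 for T cell, 2 and 0 for Nrf2, 4 and 0 for p53 and 0 and 5 for Schwann cell genes. With close arrays averaged they were 0 and 1, 0 and 0, 1 and 0, 1 and 2, 0 and 0, 1 and 0, 1 and 0, and 0 and 1.

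Rpgrip1 was higher in mixed-strain than in FVB arrays in both materials, by 2.84 ± 0.25 in culture and by 3.49 ± 0.73 (SE) in skin. The skin difference was 0.66 with strain as a covariate, where it did not pass, nor did it pass without newborn replicate 2. The skin arrays did not overlap, at 5.06 and 4.94 in newborn and 7.92 to 9.19 in 30-day skin. The spread of the skin test includes the cultures, which split by strain (8.07 and 8.16 against 5.12 to 5.42). Among the genes called between the ages, 130 were also called between mixed-strain and FVB cultures in the same direction and 74 in the opposite one, against 104.5 and 87.5 for independent lists. The culture and skin arrays of these contrasts are separate, and each contrast comes from its own fit. The fit for age has a common mean for all cultures, so its spread includes their difference by strain. Genes that differ by strain in culture are therefore harder to call between the ages. The counts given for independent lists do not allow for this. Across genes, which are not independent replicates, the contrasts correlated at 0.16.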
